A study of Mus musculus with 6 samples.

How the data were processed

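Gene expression was measured by RNA sequencing of total RNA from 6 cultures of mouse embryonic fibroblasts, grown in high-glucose DMEM with pyruvate and 10% fetal bovine serum. The authors deposited raw counts per gene, with no normalization, as 1 table of the series and as 1 table per sample. The sample tables were checked against the series table and held the same counts (0 genes differed in each of 6 libraries). The deposited series table also lists a gene length in bases, which was used only in a check of length bias. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq and the genome build mm39, without stating each tool's role. Libraries were made with a NEBNext Ultra RNA kit. Whether strands were kept is not stated, so overlapping or antisense genes cannot be separated here. Gene symbols and coordinates are those of the deposited table. The mouse reference at hand was of an older build, so it served only for synonyms of symbols (14 list members were matched that way) and for the GC content of transcripts.

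Counts per library ran from 17218621 to 25293775. A count of 0 allows up to 3 counts in that library. Ratios involving 1 to 3 counts carry 95% counting intervals, and folds against groups at 0 are lower bounds from 3 counts in each library of the group. Such intervals and bounds cover counting error only. The libraries of a group are from different cell lines and were not copies of each other (chi-square per degree of freedom 130.9 in wild type, 49.24 in early and 237.8 in late passage cells).

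Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test (robust) after TMM normalisation. All 6 libraries entered 1 fit of 3 groups, which leaves 3 residual degrees of freedom. Genes were kept by edgeR's default filter by group (a count minimum of 10 and a total minimum of 15), which left 15114 of 56748 genes. P values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05, two-sided. The errors printed are standard errors of the log2 fold change from that fit. The comparisons were early passage G127V against wild type, late passage G127V against wild type and late against early. With 2 libraries per group, a permutation of labels cannot reach 0.05, and no test of outlying libraries is possible.

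Before the data were examined, 39 gene lists were fixed, covering mitochondrial, metabolic, stress, cell cycle, matrix and cell type genes. Lists with at least 5 tested genes (34) were tested with camera from limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over the lists of a comparison. The test was repeated with the correlation estimated from the data and with the rotation test fry. Members were also adjusted over the list alone. The genes named in the text follow a rule fixed beforehand. They are the 8 protein-coding genes with the largest change in each direction among those past the threshold, with groups that do not overlap and a mean of at least 1 CPM, up to 4 members of each described list with the smallest adjusted p, up to 6 genes of each class of overlap, and Fxn, Cdkn2a, Trp53, Cdkn1a, Mki67, Tfrc, Gdf15, Atf4, Xist and Ddx3y. The remaining 2 of the 10 genes past the threshold were added after their values were seen. Genes of the overlap classes were not named because no gene passed in more than 1 comparison.

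Alternatives fixed beforehand were DESeq2 1.42.0, size factors in place of TMM, no filter on low counts, a filter at a mean of 1 CPM, only the 4 libraries of the groups compared, limma-voom with the line as a random block, no robust estimate, mitochondrial genes left out, a fold threshold of 1 on the log2 scale, each library left out in turn, and the line as a block for late against early on the 4 mutant libraries. Lines 3J and 4Z pair the early with the late libraries by name. As a check of that pairing, the difference between the lines at early passage was correlated with that at late passage across genes, which gave -0.143. The correlation within a line, estimated for the random block, was -0.0249. Neither value speaks for the pairing, which rests on the names alone.

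The procedure was tested on simulated counts with the means, spread and library sizes of these data and 200 changed genes. For early passage cells against wild type, edgeR recovered 0% of 2-fold, 32.8% of 4-fold and 71.2% of 16-fold changes on 14738 genes, with 11.5% false among the calls, and DESeq2 recovered 9%, 61.2% and 86.4% on 15114 genes with 39.9% false. For late passage cells against wild type the edgeR shares were 0%, 34.3% and 78.8% (6.2% false), and for late against early 1.5%, 34.3% and 72.7% (12.2% false). The DESeq2 shares of false calls were 41.9% and 42.6%. In 5 simulations without any change edgeR made at most 3 calls and DESeq2 at most 65. A list of 30 genes changed by 1.4-fold was found by camera with the preset correlation in each comparison, with 0 of 34 other lists called. It was missed with the estimated correlation. The simulated genes were drawn independently of each other, so lists of correlated genes were not tested. Figures were drawn with matplotlib.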

Results

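Read counts per gene were available for 6 RNA sequencing libraries from embryonic fibroblasts of mice. The series describes the cells as immortalized lines with or without the G127V change in frataxin, and gives its purpose as finding how mutant cells adapt when they are passaged for long. Frataxin, encoded by Fxn, is a mitochondrial protein of iron-sulfur cluster assembly. The libraries formed 3 groups of 2. The wild-type group held lines WT17 and WT18 at passage 8. The early passage G127V group held line 3J at passage 9 and line 4Z at passage 6. The late passage G127V group held the same lines at passages 26 and 19. No wild-type cells of late passage were included. Total counts were 17218621 in WT17, 24751173 in WT18, 25293775 in early 3J, 21683789 in early 4Z, 21350006 in late 3J and 19638693 in late 4Z. The libraries of a group came from different lines (n = 2 per group). The standard errors below come from a fit of all 6 libraries, with an estimate of spread shared by the 3 groups. They reflect differences between lines within groups, but not the spread of the compared groups alone. For late against early they do not use the pairing of libraries by line. Of 56748 genes in the table, 15114 had enough counts to be tested, and their levels are given as CPM, normalised read counts relative to library size.

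Fxn (ENSMUSG00000059363, mm39 chromosome 19, 24238817 to 24257969) was read in all 6 libraries, and its mRNA level did not differ detectably between the groups. It stood at 35.2 CPM in WT17 and 21.8 CPM in WT18, at 16.6 CPM in early 3J and 22.7 CPM in early 4Z, and at 23.0 CPM in late 3J and 43.7 CPM in late 4Z. The log2 fold change was -0.53 ± 0.42 (SE) in early passage cells against wild type, 0.23 ± 0.42 in late passage cells against wild type and 0.76 ± 0.42 in late against early. The adjusted p values were 0.492, 0.819 and 0.729. In early passage cells against wild type the value was -0.10 without WT17, -0.85 without WT18 and -0.32 without early 3J. In late passage cells against wild type it changed sign without late 4Z, to -0.28, and without WT18, to -0.10, and was 0.63 without WT17 and 0.60 without late 3J. In late against early it was 0.20 without late 4Z. A missense change need not alter the level of its mRNA, so these values do not check the genotype labels.

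The early passage libraries of lines 3J and 4Z were the closest pair, with a Pearson correlation of 0.981 across 15114 genes, which are not independent replicates. Late 3J stayed close to them (0.947 with early 3J and 0.962 with early 4Z), while late 4Z lay farther away (0.908 and 0.914). The correlation between the late libraries was 0.906, below that of WT17 and WT18 at 0.946. The lines also differed in genes of the sex chromosomes. Ddx3y and Eif2s3y, carried on the Y chromosome, had 0 counts in WT17 and WT18, whereas Ddx3y stood at 47.2 and 49.3 CPM in early 3J and early 4Z and at 51.2 and 13.8 CPM in late 3J and late 4Z. Over all genes of the Y chromosome the totals were 86 counts in WT17, 215 in WT18, 2845 in early 3J, 2754 in early 4Z, 2507 in late 3J and 1023 in late 4Z. Xist, the RNA of the inactive X chromosome, had 1819 counts in WT18, 0 in WT17, and at most 2 in a mutant library. Every comparison of G127V with wild type below was therefore also a comparison of lines that differ in sex-linked expression.

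In early passage G127V cells, 10 genes were higher than in wild type and 0 were lower. The question of this comparison is how mutant cells differ from wild type before long culture. The genes included the transcription factor Maf (ENSMUSG00000055435, mm39 chromosome 8, 116409681 to 116434533), with a log2 fold change of 3.09 ± 0.23. Maf stood at 30.9 and 26.4 CPM in WT17 and WT18 and at 244.1 and 243.3 CPM in early 3J and early 4Z. Lrrc32, a surface protein that holds latent TGF-beta, differed by 3.18 ± 0.29 and the secreted protein Ccn5 by 4.88 ± 0.38. Ndnf differed by 4.36 ± 0.34, Fam43a by 2.81 ± 0.25, the small GTPase Rasl11a by 5.15 ± 0.36 and the secreted metalloprotease Adamts9 by 4.80 ± 0.38. Bmp3, a member of the bone morphogenetic protein family (chromosome 5, 99002274 to 99032255), had 2122 counts in the early passage libraries and 2 in wild type, a ratio of 826 (95% counting interval 228 to 6820). AW551984 (ENSMUSG00000038112, chromosome 9, 39498692 to 39515699) had 1483 counts against 1, a ratio of 1150 (207 to 45600). The Y-linked Eif2s3y was at least 179-fold higher, from a floor of 3 counts in each wild-type library. All 10 genes were higher in both early passage libraries than in either wild-type library.

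Their adjusted p values ran from 0.0326 to 0.0451 (edgeR). With limma-voom and the line as a random block, 0 genes passed (smallest adjusted p 0.0509). At an unadjusted p under 0.05, 1395 genes were higher and 1594 lower, 2989 of 15114 against 756 expected by chance. DESeq2 called 790 genes as higher and 779 as lower, 1569 in all. Leaving out WT17, WT18, early 3J or early 4Z each took the count from 10 to 0, whereas leaving out late 3J or late 4Z, which enter this comparison through the shared estimate of spread, raised it to 471 or 495. Groups that did not overlap were found for 62.6% of genes, where chance gives 33.3%.

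**Figure D1:**
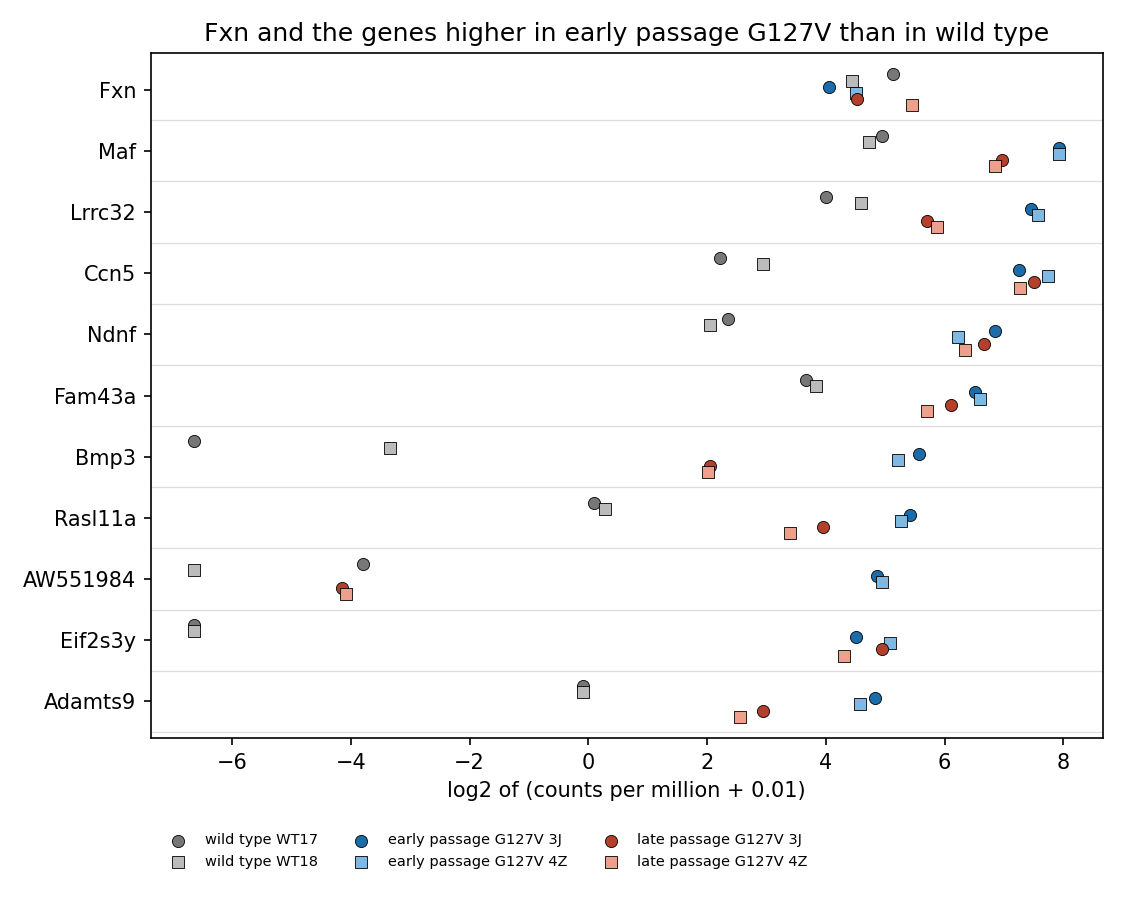
Levels of Fxn and of the 10 genes that passed the test in early passage G127V cells against wild type, as log2 of CPM plus 0.01, with 1 point per library (circles for WT17 and line 3J, squares for WT18 and line 4Z; grey wild type, blue early passage, red late passage). Each of the 10 genes lies higher in both early passage libraries than in both wild-type libraries, and Fxn in wild type overlaps with both mutant groups.

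Nuclear genes of the respiratory chain were lower as a group in early passage mutant cells than in wild type. Lists were tested against the other genes with camera at a preset correlation between the genes of a list, and with an estimated correlation the adjusted p was 0.82 for each list of this paragraph. The share of counts in genes of ribosomal proteins differed in the same direction, at 5.52% in WT17, 3.40% in WT18, 2.38% in early 3J and 2.81% in early 4Z. All 39 measured genes of complexes II to V had negative log2 fold changes (median -0.56, adjusted p = 1.93e-06), among them the ATP synthase subunit Atp5pb at -1.31 ± 0.37, cytochrome c, Cycs, at -1.22 ± 0.36 and the succinate dehydrogenase subunit Sdhb at -1.11 ± 0.30. For complex I, 32 of 35 genes were lower (median -0.52, adjusted p = 0.00765), such as Ndufa10 at -0.73 ± 0.27. Genes of the tricarboxylic acid cycle (17 of 18 lower, median -0.50, adjusted p = 0.000828) included Suclg2 at -1.24 ± 0.28 and Mdh2 at -0.91 ± 0.26. Genes of mitochondrial iron-sulfur cluster assembly (17 of 18 lower, median -0.42, adjusted p = 0.0223), of lipoate synthesis (11 of 11 lower, median -0.43, adjusted p = 0.0141) and of mitochondrial chaperones and proteases (12 of 13 lower, median -0.44, adjusted p = 0.012) included Glrx5 at -0.91 ± 0.21, Gcsh at -1.04 ± 0.32, Hspa9 at -1.27 ± 0.32 and Hspd1 at -1.34 ± 0.27. The mRNAs encoded by the mitochondrial genome went the other way, with 11 of 13 higher (median 0.58, adjusted p = 0.012), among them mt-Co3 at 1.81 ± 0.42 and mt-Nd6 at 1.07 ± 0.37. In the mitochondrial lists, 2 chaperone genes passed adjusted over the list alone and 0 genes of the others did. Without WT17 the medians were -0.25 for complexes II to V, -0.07 for complex I (adjusted p = 0.759), -0.08 for iron-sulfur assembly (0.33), -0.26 for lipoate synthesis (0.0668) and -0.22 for chaperones (0.105). Without WT18 they were -0.80 for complex I, -0.77 for iron-sulfur assembly and 0.93 for the mitochondrial mRNAs. Without early 3J they were -0.40 for complex I (0.0666), -0.32 for iron-sulfur assembly (0.0666), -0.43 for lipoate synthesis (0.0738) and 0.32 for the mitochondrial mRNAs.

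Targets of ATF4, the transcription factor of the integrated stress response, and genes of glycolysis and of G2 and M phase were also lower in early passage mutant cells, while interferon-stimulated genes were higher. With an estimated correlation the adjusted p was 0.82 for each of these 4 lists. Of 29 ATF4 targets, 24 were lower (median -0.92, adjusted p = 8.89e-05), including the serine synthesis enzyme Phgdh at -1.76 ± 0.31, asparagine synthetase, Asns, at -2.45 ± 0.44, and the mitochondrial folate enzymes Shmt2 at -1.38 ± 0.27 and Mthfd2 at -1.69 ± 0.36. Of these targets, 2 passed as higher and 12 as lower adjusted over the list alone. Glycolysis genes (17 of 20 lower, median -0.98, adjusted p = 0.0021) included enolase, Eno1, at -1.91 ± 0.32 and the lactate transporter Slc16a3 at -3.67 ± 1.03. Genes of G2 and M phase (25 of 27 lower, median -0.75, adjusted p = 1.93e-06) included Ube2c at -0.96 ± 0.22, Aurka at -0.89 ± 0.21 and cyclin B1, Ccnb1, at -1.19 ± 0.28. Interferon-stimulated genes (24 of 27 higher, median 1.53, adjusted p = 0.00019) included Ifit2 at 1.44 ± 0.31 and Mx1 at 5.01 ± 1.57. Adjusted over the list alone, 1 glycolysis gene passed as higher and 1 as lower, 3 genes of G2 and M phase passed as lower, and 0 interferon-stimulated genes passed. The interferon-stimulated median was 0.97 without WT17, 3.42 without WT18 and 0.98 without early 3J.

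Markers of endothelial cells and of adipocytes were higher in early passage mutant cells than in wild type. Of the 12 endothelial markers listed, 6 were measured and 5 were higher (median 1.89, adjusted p = 0.00609, 0.82 with an estimated correlation), including the von Willebrand factor Vwf at 5.28 ± 0.86, Eng at 3.26 ± 0.61 and the angiopoietin receptor Tek at 4.03 ± 0.82. Of them, 3 passed as higher adjusted over the list alone. The levels were low, at 7.02 and 3.12 CPM for Vwf and 4.34 and 8.52 CPM for Tek in early 3J and early 4Z. The endothelial median was above 1.89 with any library left out, from 2.09 without early 3J to 3.51 without WT17. It was 2.67 without late 3J, which is not one of the groups compared. The filter was rerun each time, so the markers measured could change, and the rise cannot be laid to single libraries. Only 4 of 12 adipocyte markers were measured, too few for the list test. All 4 passed as higher adjusted over the list alone, among them Cebpa at 2.84 ± 0.43, Plin4 at 3.61 ± 0.77 and Fabp4 at 2.10 ± 0.70.

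Genes of iron handling and of the antioxidant response showed no common direction. Of 18 genes of iron uptake, storage and export, 9 were higher and 9 lower (adjusted p = 0.652), with the ferrireductase Steap3 at 3.05 ± 0.74, ferritin heavy chain, Fth1, at 0.96 ± 0.31 and the transferrin receptor Tfrc at -1.24 ± 0.51. Among 19 targets of NRF2, 5 passed as higher and 5 as lower adjusted over the list alone (adjusted p = 0.709 for the list, whose median was -0.29 and mean 0.18). Nqo1 at 2.35 ± 0.41 and Gstm1 at 1.35 ± 0.33 were among the former and Me1 at -1.13 ± 0.25 among the latter. The stress-induced hormone Gdf15 stood at 1.68 and 1.78 CPM in wild type and at 35.7 and 24.4 CPM in early passage cells (log2 fold change 4.12 ± 1.07, adjusted p = 0.154). Atf4 itself was at -0.74 ± 0.38, Trp53 at -0.72 ± 0.24, Cdkn2a at -1.22 ± 0.42 and Cdkn1a at 0.80 ± 0.79, and the proliferation marker Mki67 was at 0.07 ± 0.43, or -0.33 without WT17. The adjusted p of these 5 genes lay between 0.199 and 0.934.

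In late passage G127V cells the nuclear genes of the respiratory chain did not pass against wild type, with the late libraries on opposite sides of the wild-type mean, while tricarboxylic acid cycle, chaperone, G2 and M phase and ATF4 target genes were lower as groups. With an estimated correlation between the genes of a list the adjusted p was 0.98 for each of the 6 lists that passed. This comparison asks which differences remained after long culture, and it also sets passages 19 and 26 against passage 8 and lines with counts for Ddx3y and Eif2s3y against lines without. The medians were -0.05 for complexes II to V (16 of 39 genes higher, adjusted p = 0.775), 0.22 for complex I (23 of 35 higher, 0.773) and -0.04 for iron-sulfur cluster assembly (8 of 18 higher, 0.867). Relative to the wild-type mean, the medians in late 3J and late 4Z were -0.30 and 0.32 for complexes II to V, -0.38 and 0.53 for complex I and -0.39 and 0.24 for iron-sulfur assembly. Without late 4Z the 3 medians were -0.30 (adjusted p = 0.00455), -0.37 (0.0512) and -0.40 (0.0693), and without late 3J they were 0.26 (0.293), 0.48 (0.00974) and 0.19 (0.354). Without WT17 they were 0.34 (0.252), 0.52 (0.00552) and 0.28 (0.641), and without WT18 -0.30 (0.046), -0.13 (0.172) and -0.16 (0.211). Tricarboxylic acid cycle genes (15 of 18 lower, median -0.44, adjusted p = 0.00783) included Suclg2 at -1.13 ± 0.28 and Mdh2 at -0.91 ± 0.26. Chaperones and proteases (11 of 13 lower, median -0.36, adjusted p = 0.0236) included Hspd1 at -1.74 ± 0.27 and Hspa9 at -1.30 ± 0.32. G2 and M phase genes (25 of 27 lower, median -0.55, adjusted p = 7.35e-05) included Ube2c at -0.90 ± 0.22 and Bub1 at -0.72 ± 0.22. ATF4 targets (24 of 29 lower, median -0.72, adjusted p = 0.00129) included Shmt2 at -1.05 ± 0.27 and Asns at -1.45 ± 0.43. All 27 interferon-stimulated genes were higher (median 1.63, adjusted p = 0.00043), such as Ifit2 at 1.34 ± 0.31, Mx1 at 4.63 ± 1.54 and Stat2 at 1.70 ± 0.70. Contractile and TGF-beta target genes (14 of 20 lower, median -0.35, adjusted p = 0.0341) included Ccn1 at -1.73 ± 0.27 and Ankrd1 at -3.06 ± 0.70.

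Adjusted over the list alone, 2 chaperone genes and 2 contractile genes passed as lower, and 0 genes of the other 4 lists did. Late 4Z decided several of these values. Without it the interferon-stimulated median was 0.11 (adjusted p = 0.662), the contractile median turned to 0.11 (0.851), the G2 and M phase median was -0.32 and that of ATF4 targets -1.17. Without late 3J the medians were -0.25 for ATF4 targets (0.671), -0.20 for chaperones (0.161) and -1.79 for contractile genes. Without WT17 they were -0.24 for the tricarboxylic acid cycle (0.113), -0.12 for chaperones (0.224), -0.35 for ATF4 targets and 1.11 for interferon-stimulated genes (0.113). Without WT18 they were -0.24 for contractile genes (0.338), -0.60 for chaperones and 3.10 for interferon-stimulated genes.

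Among single genes, 0 of 15114 passed in late passage cells against wild type (edgeR, smallest adjusted p 0.0661). At an unadjusted p under 0.05, 1180 genes were higher and 1174 lower, 2354 against 756 expected by chance, and DESeq2 called 568 as higher and 553 as lower. Leaving out late 3J or late 4Z gave 103 or 125 genes. Several genes that passed at early passage had similar log2 fold changes here, at 4.75 ± 0.38 for Ccn5 and 4.31 ± 0.34 for Ndnf. Others were nearer to wild type, at 2.07 ± 0.22 for Maf, 1.46 ± 0.27 for Lrrc32, 2.17 ± 0.24 for Fam43a, 3.52 ± 0.34 for Rasl11a and 2.85 ± 0.36 for Adamts9. Bmp3 had 171 counts against 2, a ratio of 78.7 (21.4 to 655), and Eif2s3y was at least 163-fold higher. The fibroblast marker Pdgfra, a growth factor receptor, was at 3.94 ± 0.62 (adjusted p = 0.14). Of 14 fibroblast markers measured, 8 were higher and 6 lower (median 0.23, adjusted p = 0.698 with camera). Trp53 was at -0.93 ± 0.24, Cdkn2a at -0.78 ± 0.42 and Gdf15 at 2.78 ± 1.02. Cdkn1a was at -0.70 ± 0.79 and 1.12 without WT18. Mki67 was at -0.17 ± 0.43, at 0.49 without WT18 and at 0.16 without late 4Z. Tfrc was at -0.43 ± 0.50 and Atf4 at -0.26 ± 0.37, and without late 3J they were at 0.08 and 0.14.

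Between early and late passage of the mutant lines, nuclear genes of the respiratory chain rose as a group and p53 targets, matrix genes and endothelial markers fell. With an estimated correlation the adjusted p was 0.64 for endothelial markers and 0.84 for the other 5 lists given here. This comparison bears on adaptation during long culture. The share of counts in genes of ribosomal proteins was also higher at late passage, at 2.83% in late 3J and 4.77% in late 4Z, against 2.38% and 2.81% at early passage. Of 39 genes of complexes II to V, 36 were higher at late passage (median 0.65, adjusted p = 6.63e-09), among them Atp5pb at 1.24 ± 0.37, Sdhd at 0.78 ± 0.24 and Cox7a2 at 1.04 ± 0.33. For complex I, 31 of 35 were higher (median 0.63, adjusted p = 1.07e-05), such as Ndufb11 at 0.68 ± 0.26 and Ndufs4 at 1.25 ± 0.51. Of 18 iron-sulfur cluster assembly genes, 15 were higher (median 0.41, adjusted p = 0.00676), including Abcb7 at 0.72 ± 0.26 and Fdx1 at 0.68 ± 0.25. Of 24 p53 targets, 20 were lower (median -0.60, adjusted p = 1.52e-05), including Btg2 at -1.83 ± 0.38 and Ercc5 at -1.08 ± 0.24. Cdkn1a, the p53-induced inhibitor of the cell cycle, was at -1.50 ± 0.81. Collagen and extracellular matrix genes (22 of 28 lower, median -0.65, adjusted p = 3.56e-05) included Fbln1 at -1.71 ± 0.29 and fibronectin, Fn1, at -0.94 ± 0.36. All 6 endothelial markers were lower (median -1.83, adjusted p = 3.92e-05), with Tek at -3.98 ± 0.81, Vwf at -2.20 ± 0.70 and Eng at -1.29 ± 0.57. Adjusted over the list alone, 2 p53 targets, 1 matrix gene and 1 endothelial marker passed as lower, and 0 genes of the respiratory chain or iron-sulfur assembly passed. Without late 4Z the medians were 0.19 for complexes II to V, 0.15 for complex I (adjusted p = 0.232), 0.09 for iron-sulfur assembly (0.482) and -0.33 for matrix genes (0.254). Without late 3J they were 1.04 for complex I, 0.73 for iron-sulfur assembly and -1.39 for matrix genes. Without early 3J the median of p53 targets was -0.39 and the adjusted p of iron-sulfur assembly was 0.0672. With the line as a block, fitted on the 4 mutant libraries, the matrix median was -1.03.

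Genes of glycolysis, hypoxia and sterol synthesis and ATF4 targets were also higher at late passage as groups, each with 1 line carrying most of the difference. With an estimated correlation the adjusted p was 0.87 for ATF4 targets and 0.84 for the other 3 lists. The medians in lines 3J and 4Z were 0.14 and 0.84 for glycolysis, 0.02 and 1.03 for hypoxia targets, -0.07 and 0.93 for ATF4 targets and 1.23 and -0.07 for cholesterol synthesis. Glycolysis genes (17 of 20 higher, median 0.62, adjusted p = 0.00205) included Eno1 at 1.03 ± 0.32, Pgk1 at 1.64 ± 0.54 and Slc16a3 at 2.74 ± 1.00. Hypoxia targets (15 of 17 higher, median 0.62, adjusted p = 0.0123) included Egln3 at 2.79 ± 1.07 and Pdk1 at 1.44 ± 0.59. ATF4 targets (21 of 29 higher, median 0.51, adjusted p = 0.0429) included Phgdh at 0.88 ± 0.30 and the cystine transporter Slc7a11 at 1.74 ± 0.64, with Ppp1r15a at -1.37 ± 0.33. Cholesterol synthesis genes (19 of 20 higher, median 0.42, adjusted p = 7.08e-05) included Pmvk at 0.98 ± 0.37 and Idi1 at 1.31 ± 0.54. Adjusted over the list alone, 0 genes of these 4 lists passed. Without late 4Z the medians were 0.10 for glycolysis (adjusted p = 0.689), -0.04 for hypoxia targets (0.349) and -0.02 for ATF4 targets (0.232). Without late 3J those of hypoxia and ATF4 targets were 1.01 and 0.97, and without early 4Z the ATF4 median was 0.40 (0.122). The cholesterol synthesis median was -0.07 without early 3J (0.7) and 1.18 without early 4Z.

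Interferon-stimulated genes went in opposite directions in the lines, with libraries paired by line name. In line 3J, 0 of 27 were higher at late passage than at early passage (median -2.02), and in line 4Z all 27 were higher (median 1.48). Contractile and TGF-beta target genes were higher at late passage in line 3J (15 of 20, median 0.62) and lower in line 4Z (4 of 20 higher, median -1.69). The group comparison gave a median of 0.12 for interferon-stimulated genes (adjusted p = 0.543) and 0.05 for contractile genes (0.268), although camera placed both lists on the lower side. With an estimated correlation the adjusted p was 0.95 and 0.88. Without late 4Z the medians were -1.68 and 0.55, and without late 3J 0.76 and -1.36. Without early 4Z the interferon-stimulated median was -0.45, and without early 3J it was 0.71. The corresponding contractile medians were 0.19 and -0.27. With the line as a block they were -0.15 (0.469) for interferon-stimulated and -0.42 (0.252) for contractile genes.

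**Figure D2:**
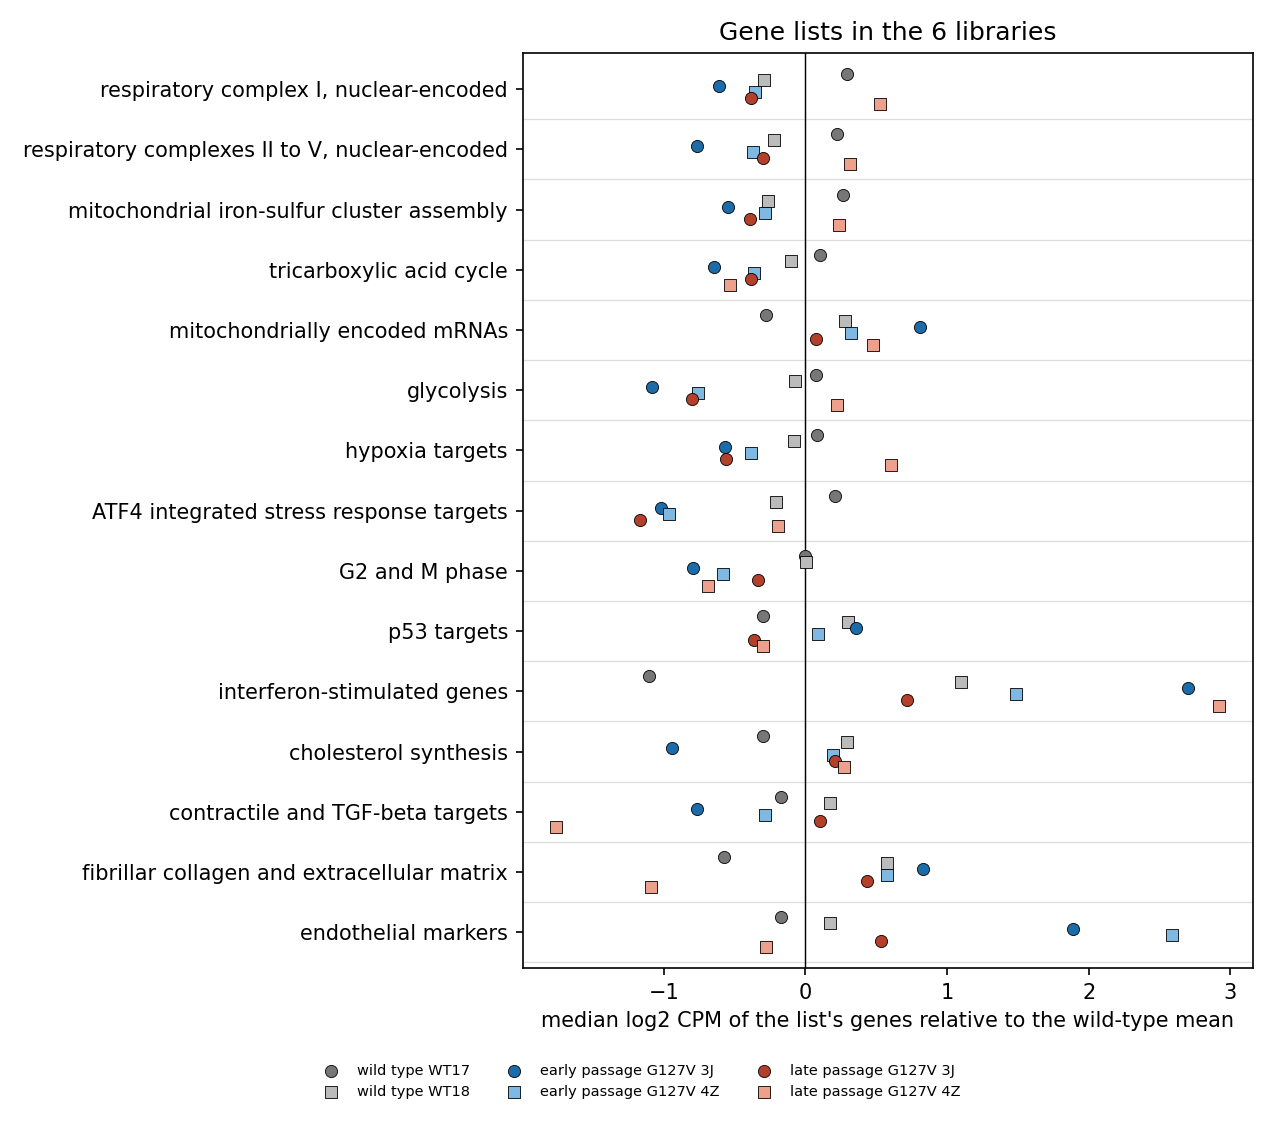
Median log2 CPM of the genes of 15 lists in each of the 6 libraries, relative to the mean of the wild-type libraries (circles for WT17 and line 3J, squares for WT18 and line 4Z; grey wild type, blue early passage, red late passage). Late 4Z lies apart from late 3J for interferon-stimulated, contractile, hypoxia and ATF4 target genes, and the early passage libraries lie highest for endothelial markers.

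Among single genes, 0 of 15114 passed in late against early passage cells (edgeR, smallest adjusted p 0.116). At an unadjusted p under 0.05, 527 genes were higher and 435 lower, 962 against 756 expected by chance, and DESeq2 called 30 as higher and 125 as lower. With the line as a block the count was also 0. AW551984 had 1483 counts at early and 2 at late passage, a ratio of 627 (173 to 5190). Igfbp3, an insulin-like growth factor binding protein, was at -5.10 ± 0.62 (adjusted p = 0.516) and Igfbp4 at -1.86 ± 0.63 (0.729). Both belong to a list of 31 senescence-associated secreted factors that did not pass (adjusted p = 0.759). Genes that passed at early passage were at -3.38 ± 0.48 for Bmp3, -1.95 ± 0.33 for Adamts9, -1.72 ± 0.27 for Lrrc32, -1.64 ± 0.31 for Rasl11a, -1.02 ± 0.21 for Maf and -0.64 ± 0.24 for Fam43a. They were selected as high in the early libraries, which enter this comparison too, so part of a fall can come from that selection. Ccn5 and Ndnf, which also passed there, differed from wild type by similar amounts at early and late passage. Cdkn2a was at 0.43 ± 0.42, Trp53 at -0.21 ± 0.24 and Gdf15 at -1.33 ± 0.95. Tfrc was at 0.81 ± 0.51, Atf4 at 0.48 ± 0.37, Mki67 at -0.24 ± 0.43 and Ddx3y at -0.57 ± 0.63, and without late 4Z they were at -0.08, -0.17, 0.03 and 0.06.

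The comparisons share libraries, so genes called in more than 1 of them were counted against simulated data. The simulation drew each gene and library independently, without lines shared by early and late passage. Its ranges are therefore likely too narrow as a reference for chance. The same mutant lines and wild-type libraries enter both comparisons with wild type, so kept genes cannot be told apart from lasting differences between lines. Genes were counted as late-only if they passed against wild type at late but not at early passage. They also had to pass in late against early in the same direction. At adjusted p the 10 genes of early passage cells gave 0 genes that were reversed in late against early and 0 kept in late against wild type, and 0 genes were late-only. The corresponding DESeq2 counts were 92, 698 and 35. At unadjusted p under 0.05, 456 genes were reversed, where independent lists give 40.1 for genes higher and 55.6 for genes lower at early passage, and simulated data without any change gave 164 on average (137 to 187). For kept genes the count was 1435, where independent lists give 108.9 and 123.8 and the simulation 165 (147 to 187). Late-only genes, as defined above, numbered 184, against 153 (130 to 178) in the simulation. Over all 15114 genes the correlation of early against wild type with late against early was -0.535, where the simulation gave -0.499 (-0.517 to -0.477), and 67.5% of genes had opposite signs, where it gave 66.6% (66.0% to 67.0%). The covariance of the same log2 fold changes was -0.509, where the simulation gave -0.219 (-0.234 to -0.207). The correlation of early with late passage cells, each against wild type, was 0.759, where the simulation gave 0.506. With no library shared between the differences, the correlation across genes of early minus wild type with late minus early lay between -0.337 and -0.208 in 4 combinations of lines. The early libraries of the lines correlated at 0.981, so what they have in common enters both differences with opposite sign. These correlations are therefore no independent evidence of reversal.

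With libraries paired by line name, the change from early to late passage had little in common between the lines. The check of that pairing gave -0.143, so expression itself does not speak for it. Across 15114 genes the late minus early differences of lines 3J and 4Z correlated at 0.097, and 55.2% of genes had the same sign. Expression of whole chromosomes also shifted between passages. Genes of chromosome 3 were higher at late passage in both lines, by a median log2 of 0.27 in line 3J and 0.59 in line 4Z relative to all autosomes. The same chromosome stood at -0.47 in early passage cells and at -0.01 in late passage cells relative to wild type. Chromosome 9 was at 0.29 in line 3J and -0.14 in line 4Z. Subtracting the median of each chromosome from every library left 13, 6 and 10 lists past the threshold, where 12, 6 and 10 had passed. It moved the median of mitochondrial chaperones in early passage cells against wild type to -0.72, and that of contractile genes to -0.91 in late passage cells against wild type (adjusted p = 0.0359) and to -0.50 in late against early (0.135). That alternative was chosen after the data were seen.

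**Figure D3:**
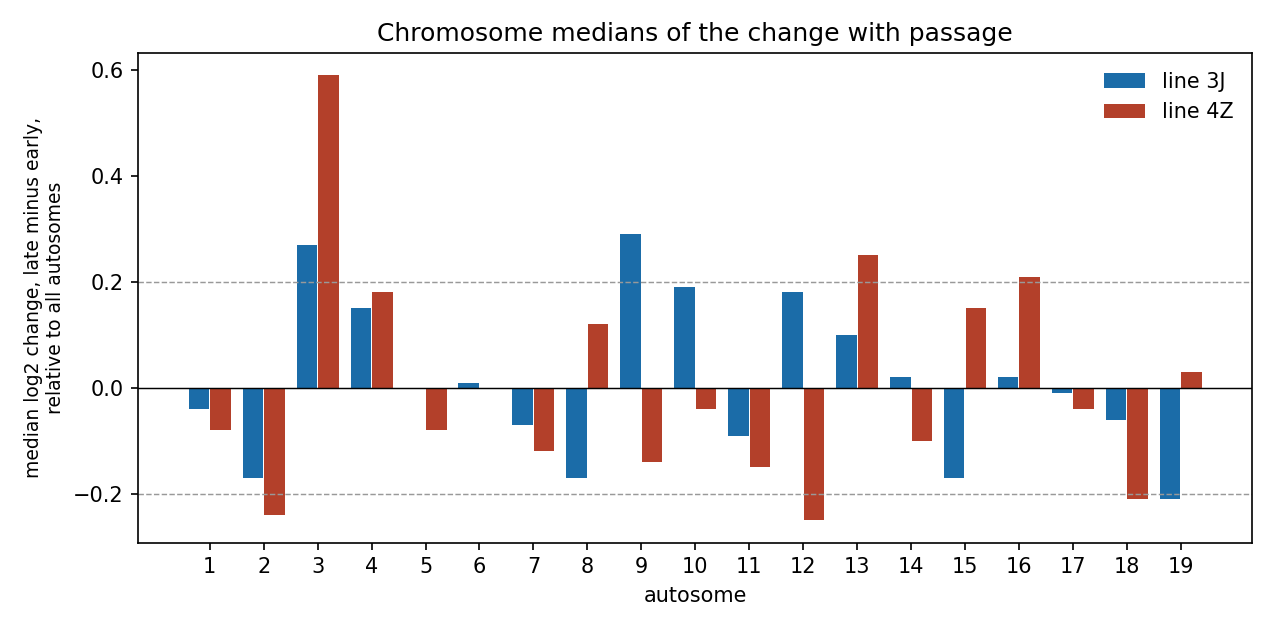
Median log2 difference between late and early passage for the genes of each autosome, relative to all autosomes, in line 3J (blue bars) and line 4Z (red bars), with dashed lines at 0.2 and -0.2. Chromosome 3 is the only autosome beyond 0.2 in both lines, at 0.27 and 0.59.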

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

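Of the tests in this part, those of chromosome gain or loss, of embryo sex and of library size were planned before their results were seen, and those of reads from X-linked homologs, of a single X chromosome in WT17, of GC content and length, of gene clusters and of mixed cells were chosen afterwards, those of GC content and gene clusters in place of planned versions and that of mixed cells in place of earlier versions, whose bounds had left an explanation open.

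Paired by name, lines 3J and 4Z moved in opposite directions from early to late passage for 5 of 42 genes and 4 of 12 lists. These are the genes and lists described for late against early, without the senescence-associated factors. Other lists also went in opposite directions, among them senescence-associated factors, G2 and M phase and tricarboxylic acid cycle genes. The difference was not tested because each line has 1 library per passage. The log2 differences of late minus early in lines 3J and 4Z were 0.06 and -0.49 for Trp53, 0.02 and -0.58 for Mki67, -0.17 and 0.93 for Atf4, 0.11 and -1.83 for Ddx3y and -0.02 and 3.65 for Egln3. The list medians were 1.23 and -0.07 for cholesterol synthesis, -0.07 and 0.93 for ATF4 targets, -2.02 and 1.48 for interferon-stimulated genes and 0.62 and -1.69 for contractile and TGF-beta targets.

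The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had counts in the mutant lines and 0 in the wild-type lines, where the totals over all genes of the Y chromosome were 86 in WT17 and 215 in WT18. For these 4 genes, reads of X-linked homologs counted as Y-linked are argued against, since they had 0 counts in the wild-type libraries, where their X-linked homologs stood between 29.2 and 567 CPM. Different sex of the embryos accounts for 3 of 4 lines (Xist and none of the 4 Y-linked genes in WT18, the opposite in 3J and 4Z) and stays open for WT17, which had neither. A candidate explanation for WT17 is 1 X chromosome without a Y: the median log2 ratio of 4 genes that escape X inactivation was -0.58 against WT18, at percentile 7.9 of 10000 random X-linked sets, which leaves it open. Genotype and sex-linked expression cannot be told apart in these lines, and no biological explanation beyond that was tested.

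Expression of whole autosomes shifted with passage, beyond 0.2 on the log2 scale for 3 autosomes in line 3J and 6 in line 4Z. All 9 medians exceeded every median of 1000 random assignments of genes to chromosomes (at most 0.101 in line 3J and 0.178 in line 4Z). Gain or loss of chromosomes in part of the cells would give such shifts. WT17 minus WT18, at the same passage, was -0.26 on chromosome 2, -0.21 on chromosome 16 and 0.21 on chromosome 18. Apart from chromosome 3 in line 4Z, at 0.59, the 9 medians were 0.21 to 0.29 in size. Shifts near that size were therefore also present between the wild-type lines and are not specific to passage. On chromosome 3 the wild-type lines differed by 0.02. A few clusters of neighbouring genes are argued against on chromosome 3, where 10 of 10 segments over both lines lay above random gene sets of their size (0.19 to 0.78). At an earlier cut of 0.2, the segment at 0.19 in line 3J would have left this open. A bias by GC content or gene length is argued against there as the whole cause. After correction the medians of chromosome 3 stayed at 0.21 in line 3J and 0.59 in line 4Z. The first of these lies close to the cut of 0.2. For the other chromosomes 4 of 7 medians stayed beyond 0.2, so a part due to GC content or length remains open. Relative to the wild-type mean, chromosome 3 stood at -0.47 in early 3J, -0.45 in early 4Z, -0.15 in late 3J and 0.14 in late 4Z. On every autosome the medians of early 3J and early 4Z differed by at most 0.06. A difference shared by the early libraries therefore cannot be told apart here from a change within each line. A change in chromosome number may underlie the shift of chromosome 3, as a hypothesis that RNA counts alone do not settle.

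The late library of line 4Z stood apart from the other mutant libraries. Its size is argued against, since the mean correlation with the other 3 was 0.905 after all libraries were thinned to the smallest total and 0.909 before, while the others stayed between 0.936 and 0.951. The 4 Y-linked genes in late 4Z had a median level of 41.2% of early 4Z, and cells without a Y chromosome could account for that median only at a share of 58.8%. The genes differed, however. From early to late 4Z, Ddx3y went from 50.96 to 14.31 CPM and Eif2s3y from 35 to 20.52 CPM (without TMM). The share needed therefore differs between the genes, and 58.8% stands for their median alone. Cells of a wild-type line mixed into the culture are argued against as the whole cause, since a mixture lies between the levels of its parts. Of 2494 genes at 100 CPM or more in late 4Z, 36 were more than 4 times above both early 4Z and WT17, and 42 more than 4 times above both early 4Z and WT18. At a share of 58.8% such cells would also bring their abundant transcripts. Thy1 stood at 254 CPM in WT18 and at 0 in late 4Z. Ndn and Peg3 stood at 85.6 and 48.3 CPM in WT17 and at 0 in late 4Z. Both also fell with passage in line 3J, from 2.54 and 2.61 CPM in early 3J to 0.324 and 0.231 CPM in late 3J. Whether cells of WT17 would lose them with passage as well was not tested. Ndn and Peg3 therefore do not settle whether such cells were present. All of these genes were chosen after their values were seen. Of genes at 100 CPM or more in WT17, 4 of 2352 stood below 5.88% of that level in late 4Z. For WT18 the count was 10 of 2440. The limit lies far below the 58.8% that such a share would bring, and no other mutant library was counted for reference. These counts therefore do not speak for or against a mixture. A smaller share beside other changes stays open. Whether the library carries a wrong label also stays open, and a biological difference in the adaptation of the lines was not tested.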

How the results depend on the processing

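Subtracting chromosome medians and the crossed pairing (late 3J with early 4Z and late 4Z with early 3J) were chosen after the data were seen. The counts of genes depended on the test, the filter and the libraries. DESeq2 gave 1569, 1121 and 155 genes for early against wild type, late against wild type and late against early, and the classes of reversed, kept and late-only genes held 92, 698 and 35. Without the filter on low counts the counts were 2189, 1568 and 625 and the classes 344, 1045 and 129. There edgeR's prior degrees of freedom became infinite for all 28000 genes, against a median of 3.04 with the filter, so the spread of each gene was no longer used. For early against wild type the 4 libraries alone gave 471 genes and voom with a random line block 0; the cause was not tested. All 10 genes were also called by DESeq2, without the filter and with 4 libraries. For late against early the count was 0 with the line as a block and with the crossed pairing. With a library left out, the counts ranged from 0 to 495 for early against wild type and from 0 to 125 for late against wild type, kept genes from 0 to 106, and lists in late against early from 8 to 17. Of the lists, 12, 6 and 10 passed with the preset correlation and 0, 0 and 0 with the estimated correlation or the rotation test. The self-test missed a changed list with the estimated correlation as well. Its genes were drawn independently, so it cannot show whether the preset correlation of 0.01 holds for these lists. In early against wild type the estimated correlation ran from -0.142 for endothelial markers to 0.842 for cholesterol synthesis. It was 0.743 for complex I and 0.583 for complexes II to V.

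In late against early, subtracting chromosome medians took the median of contractile genes from 0.05 to -0.50 and that of interferon-stimulated genes from 0.12 to -0.12, and the line block on the 4 mutant libraries took them to -0.42 and -0.15. No other named gene, and no other list run under these settings, changed sign where all libraries of its comparison were kept. The lists of iron handling, NRF2 targets and senescence-associated factors were not run under them. With a library left out, the ranges of values that changed sign were, for late against wild type, -0.28 to 0.63 for Fxn, -1.46 to 1.12 for Cdkn1a, -0.60 to 0.49 for Mki67, -1.28 to 0.084 for Tfrc, -0.86 to 0.14 for Atf4, -1.79 to 0.11 for contractile genes, -0.30 to 0.34 for complexes II to V, -0.37 to 0.52 for complex I and -0.40 to 0.28 for iron-sulfur assembly. For late against early they were -0.63 to 0.033 for Mki67, -0.084 to 1.33 for Tfrc, -0.17 to 0.89 for Atf4, -1.83 to 0.06 for Ddx3y, -0.072 to 1.18 for cholesterol synthesis, -0.043 to 1.01 for hypoxia targets, -0.019 to 0.97 for ATF4 targets, -1.68 to 0.76 for interferon-stimulated genes and -1.36 to 0.55 for contractile genes. For early against wild type Mki67 ranged from -0.33 to 0.73. The group left with 1 library is assumed there to vary like the others. The cause was not tested. At this depth a gene with 0 counts in a library can stand at up to 3 counts.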

Other observations

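The genes of this paragraph were chosen after their values were seen, and the CPM values are given for WT17, WT18, early 3J, early 4Z, late 3J and late 4Z in that order. Haptoglobin, Hp, stood at 0.124, 0.133, 212, 68.3, 2.41 and 256 CPM and the copper protein ceruloplasmin, Cp, at 1.49, 1.95, 77.9, 22.5, 1.53 and 231 CPM. The matrix proteoglycan decorin, Dcn, was at 7.95, 2.44, 242, 49.4, 0.972 and 503 CPM. Complement C3 was at 332 CPM in early 3J, 13.2 CPM in late 3J and 434 CPM in late 4Z. The transcription factor Tfap2b stood at 0, 0, 49.6, 55.6, 115 and 7.55 CPM and the transcription factor Lmx1b at 0, 0, 47.5, 51.1, 84 and 2.21 CPM. Igfbp2 reached 2050 CPM in late 3J against 4.22 CPM in late 4Z, and elastin, Eln, was at 112 and 0.147 CPM. The surface glycoprotein Thy1, a marker of many fibroblasts, was at 254 CPM in WT18, 1.62 CPM in WT17 and at most 0.0368 CPM in the mutant libraries.

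Several imprinted genes, expressed from the maternal or the paternal copy alone, were low at late passage in both lines. H19 stood at 98.2 and 70 CPM in early 3J and early 4Z and at 6.81 and 14 CPM in late 3J and late 4Z, Dlk1 at 214 and 55.8 against 2.08 and 0.638 CPM, and Mest at 49 and 50.6 against 2.55 and 1.03 CPM. Cdkn1c, also imprinted, showed no such fall, at 10.3 and 13.4 against 10.9 and 10.9 CPM. The hypothesis that imprinted genes fall as a class with passage was tested, after these values were seen, on the members of a list of 44 imprinted genes whose values had not been seen (23 measured). Their median log2 difference in late against early was -0.12, within the middle 95% of 10000 random lists matched on expression (-0.21 to 0.34), with 7 genes higher and 16 lower. With camera the p was 0.0132 at the preset correlation and 0.137 at an estimated correlation. In late passage cells against wild type their median was -0.36, outside the random lists (-0.28 to 0.41), with p of 0.0687 and 0.228. The median of late minus early was 0.03 in line 3J and -0.67 in line 4Z. All 32 measured genes together had a median of -0.78 in late against early (p of 2.95e-06 and 0.0141), which is no independent evidence because it includes the genes that prompted the test. A shift of the class therefore stays open.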
